A study of Mus musculus with 104 samples.

How the data were processed

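The series holds 104 arrays of RNA from mouse muscle stem cells (satellite cells), taken from Per1-Venus reporter mice on a C57BL/6J background. Per the labels' protocols, mice of 2 age groups were fed either a control diet without limit or a calorie restricted diet (CR) with 30% less food. The diet phase lasted 25 weeks and followed 3 weeks of adaptation in which the food of the CR mice was reduced by 10% a week. The age groups were 19 to 29 and 55 to 69 weeks old when the adaptation started, which puts their ends at 47 to 57 and 83 to 97 weeks. Cells were collected at 6 times of day, T0 to T20 in steps of 4 h. Per the labels' protocols, 25 ng of total RNA was amplified with WTA2 in 17 cycles, and 8 µg of cDNA was fragmented and biotinylated for the array. The gate by which the cells were isolated is not given in the sources used here.

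Arrays were grouped by their titles into 4 arms of age and diet. The adult control arm had 22 arrays, adult CR 32, aged control 24 and aged CR 26. Cells of an arm and a time point held 4 to 6 arrays, except adult control T20 with 1. The labels disagree in 2 respects. The design text gives 4 mice per time point and diet group, while 1 to 6 arrays were deposited per arm and time, and whether arrays were added or left out is not given in the sources used here. All 22 arrays titled adult control carry an age tag of 83 to 97 weeks, the age of the aged mice. The titles were used, and the age effect was also taken within CR, where titles and tags match. The titles call the arrays biological replicates. Per the series' design text, a mouse of each diet group was collected on a day. Replicate numbers are shared between diets, but no label says that a number marks a shared mouse or day, so arrays were not paired in the main tests.

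The deposited values are RMA values per the submitters' processing notes, with no version given. They range from 1.19 to 12.8, which is the range of a log2 scale, and the log2 base is inferred from these deposited values because no header states it. RMA compresses differences near the floor of the scale, so differences of dim genes are understated. Whether the authors applied a batch correction or a filter is not given in the sources used here. Arrays have no read depth, so the number of arrays limits the precision.

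Of 45141 probe sets, 28898 had 1 gene symbol in the platform annotation, 551 had several and 15692 had no listed gene, and 28689 of the former matched the RefSeq gene table of assembly GRCm38.p6 by Entrez number. That table was used for names and for neighbouring genes only. Probe sets with a mean below the 40th percentile (log2 4.50) were left out, and the probe set with the highest mean was kept per gene, which left 11853 genes. The clock genes Nr1d1 and Cry1 were not analysed here, and some other items are not reported here.

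All 104 arrays were fitted together in limma 3.58.1 (R 4.3.3, lmFit and eBayes) with a day mean, a cosine and a sine of 24 h period for each arm. A gene was called rhythmic in an arm by limma's moderated F test of its cosine and sine. Levels were compared by limma's moderated test of the difference between day means, and rhythms by the F test of the differences between cosine and sine terms. Adjusted p values are Benjamini-Hochberg values over the 11853 genes, with 5% as the threshold. The amplitude is the distance from day mean to peak of the fitted curve on the log2 scale, and errors of fitted values are standard errors (SE). In all, 38 gene lists were fixed before the data were examined. Their levels were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and their rhythmic members were counted with a one-sided Fisher's exact test, each adjusted over the lists. A list's score in an array is the mean log2 value of its members.

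Named genes followed a rule fixed at the same stage. It takes all clock genes, the 8 rhythmic genes of largest amplitude per arm, and the 8 called genes with the largest difference each way whose sign held in at least 5 of the 6 time points. It also takes the 8 called genes of smallest p for a rhythm difference, up to 4 members of each list that passed, and the brightest markers of each cell type. Where a gene outside the rule is named, the text says so.

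Alternatives were another filter on dim probes or none, the mean of a gene's probes, separate fits per comparison, time as 6 levels, omission of T20, matched numbers of arrays, array weights, added quantile normalization, the first residual principal component as a covariate, a replicate block, a rank-based cosine test, an estimated correlation between list members, and omission of each array in turn. The scores of 3 cell type lists as covariates were added after seeing the data. The tests were run on simulated values with the real genes' means and spread and 400 changed genes. For the age effect in the control diet, 62% of simulated differences of 0.25 and 98% of those of 0.5 on the log2 scale were called. In adult control, 28% of simulated amplitudes of 0.25 and 82% of those of 0.5 were called, against 44% and 92% in adult CR. For the rhythm difference between diets in aged mice, 64% of lost amplitudes of 0.5 and 96% of those of 0.75 were called. Figures were drawn with matplotlib 3.10.9.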

Results

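Muscle stem cells were profiled over the day in 4 arms, adult and aged mice on a control diet or under calorie restriction (CR), to ask how age and diet change the cells' daily expression rhythms and their mean expression. The arms held 22 adult control, 32 adult CR, 24 aged control and 26 aged CR arrays, with values for 11853 genes. Markers of muscle stem cells were bright. Gpx3 averaged 12.4 on the log2 scale, Sdc4 12.2 and Fgfr4 11.1, and Myod1, the regulator of myogenic commitment, averaged 10.6. Markers of other cell types were also measured. Among the brightest were Gsn at 10.9 and Dpt at 10.8 for fibroadipogenic progenitors, Acta2 at 10.8 for pericytes and smooth muscle, and Pmp22 at 10.8 and Mbp at 10.4 for Schwann cells. Endothelial Cdh5 averaged 7.17, macrophage Cd68 7.91, lymphocyte Cd79a 7.50, neutrophil S100a9 5.52, erythroid Hba-a1 7.40, tenocyte Thbs4 7.66, adipocyte Retn 5.28 and myofibre Atp2a1 8.29. No columns were identical, and the lowest correlation between arrays of the same arm and time was 0.940.

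The first comparison asked which genes follow a daily rhythm in each arm. The molecular clock ran in all 4 arms. In adult control cells, Arntl, the clock's activator, peaked at 23.3 h ± 0.54 (SE, 22 arrays) with a 4.62-fold range from trough to peak. Its targets peaked in the opposite part of the day, with Nr1d2, a repressor of Arntl, at 8.82 h ± 0.31, the output factor Dbp at 10.1 h ± 0.34 and the repressor Per3 at 12.1 h ± 0.54. Of 17 measured clock genes, 12 were rhythmic in adult control, 16 in adult CR, 14 in aged control and 12 in aged CR, and 12, 16, 15 and 13 when adjusted over the list alone. The Fisher's exact test gave adjusted p = 2.70e-07, 1.92e-08, 4.97e-10 and 3.99e-05 in that order. Clock itself had limma adjusted p = 0.932 in adult control and 7e-04 in adult CR, and its rhythm difference between these arms did not pass (limma adjusted p = 0.72).

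**Figure D1:**
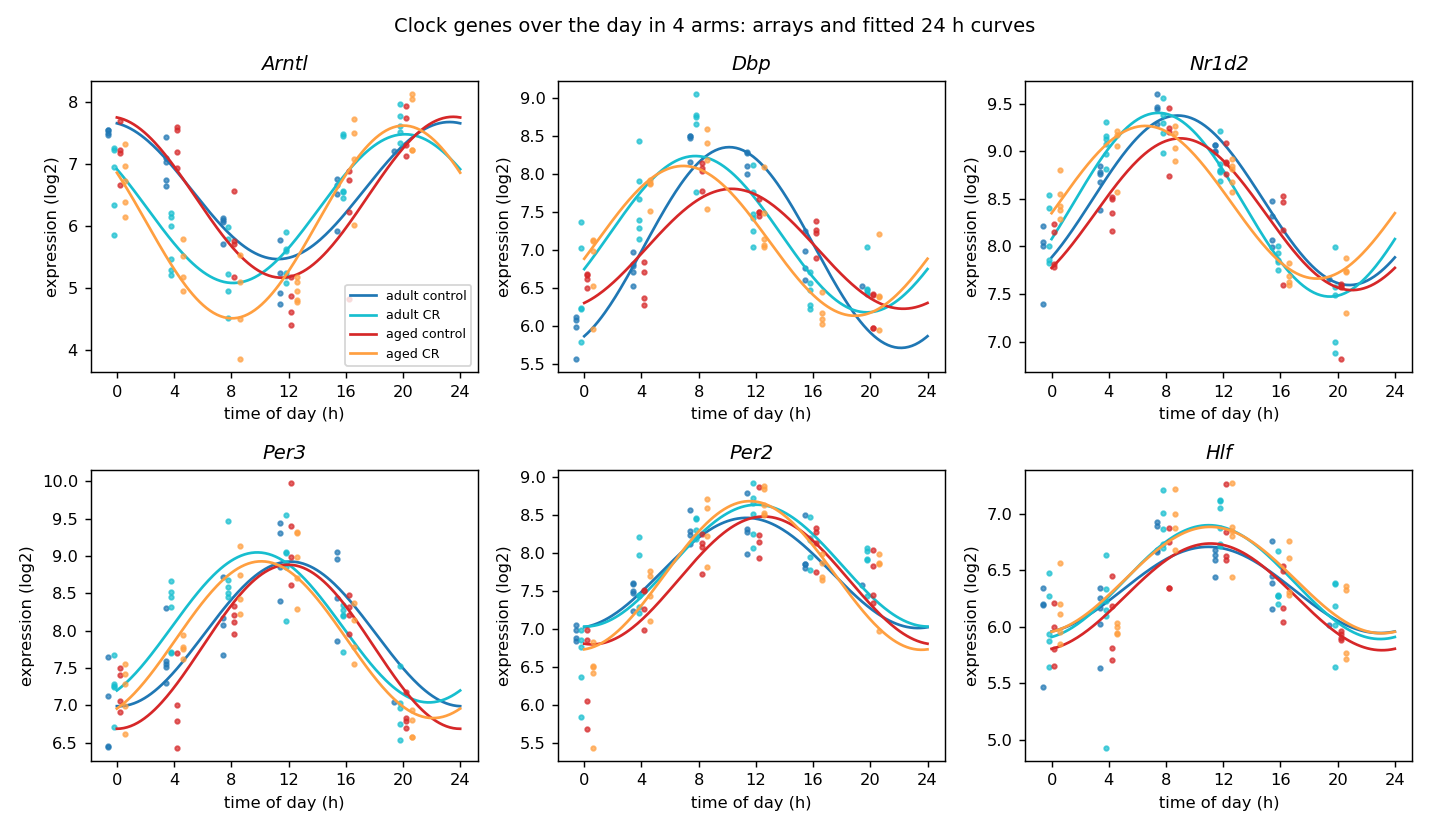
Expression (log2) of 6 clock genes against time of day (h). Points are arrays, offset sideways by arm, lines are the fitted 24 h curves of the 4 arms, and the Arntl curves peak at 23.3 h in adult control and 20.1 h in adult CR.

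Genome-wide, limma called 1256 rhythmic genes in adult control, 2650 in adult CR, 1276 in aged control and 1951 in aged CR (Benjamini-Hochberg, 5%). The largest amplitudes in adult control belonged to Sphk2 (1.85 ± 0.13), the fast-fibre gene Tnnc2 (1.44 ± 0.36), Dbp (1.32 ± 0.13) and the tenocyte marker Thbs4 (1.30 ± 0.27). Sphk2 also led in adult CR (1.52 ± 0.10), Tnnc2 in aged control (1.56 ± 0.33) and Arntl in aged CR (1.55 ± 0.14). The annotated span of Sphk2 overlaps that of its neighbour Dbp, so its signal cannot be assigned with certainty. In adult control arrays the tenocyte and myofibre scores had SDs of 0.70 and 0.54, against 0.15 for the muscle stem cell score. Whether Tnnc2 and Thbs4 follow varying fibre or tendon material was not tested. With 21 arrays in each arm, the counts were 1108, 1453, 952 and 1232, and their summed excess under CR was reached in 6 of 100 exchanges of diet labels, the real grouping included. A rank-based cosine test called 10, 1525, 197 and 543 genes, and without the T20 arrays 836 genes were called in aged control.

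**Figure D2:**
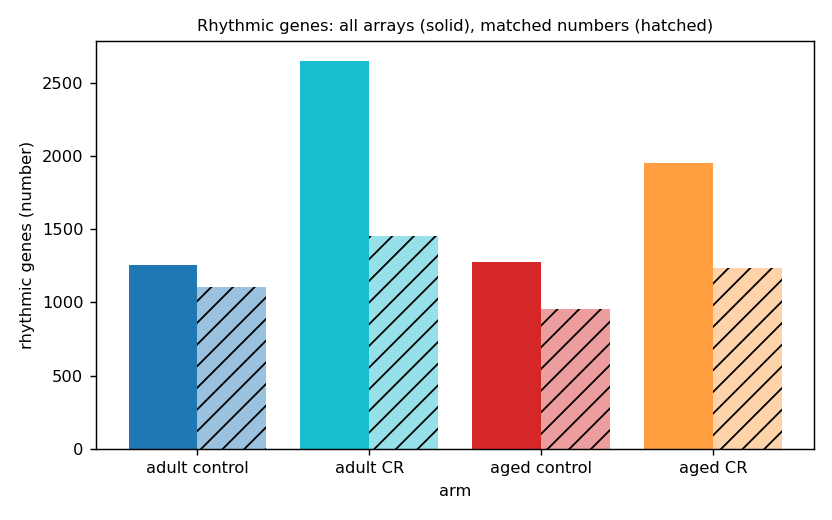
Number of rhythmic genes (limma, Benjamini-Hochberg 5%) per arm. Solid bars use all arrays (1256, 2650, 1276 and 1951 genes from left to right), and hatched bars use 21 arrays per arm (1108, 1453, 952 and 1232).

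Other gene groups were rhythmic beside the clock. Among glucocorticoid-induced genes, 6 of 12 were rhythmic in adult control, 10 in adult CR and 8 in aged CR (11, 10 and 10 when adjusted over the list alone), with Fisher's exact adjusted p = 0.014, 0.00025 and 0.0027. In aged control it was 4 of 12 (5 when adjusted over the list alone), which did not pass (Fisher's exact adjusted p = 0.25). The list includes Per1, which also counts as a clock gene. Tsc22d3, a glucocorticoid target, peaked at 12.7 h ± 0.89 in adult control. Schwann cell markers were rhythmic in 4, 6 and 5 of 7 cases in the same arms (5, 6 and 5 when adjusted over the list alone), with adjusted p = 0.043, 0.0089 and 0.016 by Fisher's exact test, and in 3 of 7 in aged control (5 when adjusted over the list alone), which did not pass (Fisher's exact adjusted p = 0.25). In adult control the rhythm call of S100b was lost in 7 omissions of a single array and that of Pmp22 in 4. Fisher's exact test takes members as independent, whereas the Schwann markers varied together within groups (mean correlation 0.268). Mbp, a myelin protein gene, peaked at 12.4 h ± 0.77 in adult control, whereas Ncam1 peaked at 21.1 h ± 0.63 in adult CR. In aged CR, 8 of 13 sterol and fatty acid synthesis genes were rhythmic (9 when adjusted over the list alone, Fisher's exact adjusted p = 0.0040). They included Scd1, a fatty acid desaturase, at 19.1 h ± 0.52 and Fdft1, a squalene synthase, at 18.2 h ± 0.59. Also in aged CR, 10 of 23 extracellular matrix genes were rhythmic (11 when adjusted over the list alone, Fisher's exact adjusted p = 0.016), among them the collagens Col5a1 at 21.1 h ± 0.47 and Col5a3 at 23.0 h ± 0.50.

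The overlap of rhythmic genes was compared between arms that share no arrays. Arms may still share collection days, and the numbers for independent lists allow for no such shared factor. Adult control and aged control had 455 rhythmic genes in common, against 135 for independent lists, and 78.7% of them peaked within 2 h of each other (16.7% for random times). Adult CR and aged CR shared 929 against 436. Between diets, 708 genes were shared in adult mice against 281, and 484 in aged mice against 210. In all 4 arms, 217 genes were rhythmic. Between the control arms, separate fits gave 289 genes in common, the Schwann score as a covariate 259, and the rank-based test 8. Separate fits called 963 genes in adult control and 902 in aged control, and the rank-based test called far fewer. Independent lists share fewer genes where fewer are called, and that number was not computed for these alternatives.

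The question whether age changes rhythms was tested on the curves themselves. No shift of the clock genes with age was detected. Over 11 clock genes rhythmic in both control arms, the mean shift with age was -0.06 h (permutation p = 0.867, adjusted p = 0.867 over 4 such tests). Within CR it was -0.16 h (permutation p = 0.558, adjusted p = 0.744). Arntl shifted by 0.24 h ± 0.68 in the control diet. Genome-wide, limma found 0 genes with a rhythm difference between ages in the control diet, with 479 at an unadjusted p under 0.05, and 1 without the filter on dim probes. All adult control arrays carry the age tag of the aged mice, so if the tags hold, the control diet comparison sets aged against aged mice. Within CR, 1 gene had a rhythm difference between ages. It was Fzd7, a Wnt receptor, whose peak lay at 7.4 h in adult and 19.2 h in aged cells (limma adjusted p = 0.020). Within CR, 1169 genes had an unadjusted limma p under 0.05. The Fzd7 call was lost without each of 6 arrays and without the T20 arrays (0 calls). No gene was called with the mean of a gene's probes, matched numbers of arrays or array weights either. More were called with time as 6 levels (2) and with the first residual component as a covariate.

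Clock genes peaked earlier on average under CR. The fitted peak of Arntl lay 3.13 h ± 0.66 earlier than in the control diet in adult cells and 3.46 h ± 0.54 earlier in aged cells. That of Dbp lay earlier by 2.37 h ± 0.50 and 3.38 h ± 0.70, Per3 by 2.30 h ± 0.67 and 1.88 h ± 0.61, and Nr1d2 by 1.36 h ± 0.40 and 2.45 h ± 0.48. Hlf, a clock output factor, shifted by 0.02 h ± 1.09 and -0.02 h ± 0.99, and Per2 by 0.72 h ± 0.82 and -0.97 h ± 0.70. Singly, the rhythm difference passed limma's test for Dbp in adult and aged cells (adjusted p = 0.040 and 0.019) and for Arntl and Nr1d2 in aged cells (adjusted p = 0.00069 and 0.015). It did not pass in adult cells for Arntl (limma adjusted p = 0.083) and Nr1d2 (limma adjusted p = 0.58), nor for Per3 (limma adjusted p = 0.58 in adult and 0.23 in aged cells). Over 11 clock genes rhythmic in both diets, the mean shift was -1.503 h in adult cells, with 9 earlier and 2 later (two-sided permutation p = 0.00017, adjusted p = 0.00034). In aged cells it was -1.83 h with 11 of 11 earlier (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 4e-05). The median shift of all 708 genes rhythmic in both diets was -0.09 h in adult cells, and that of 484 genes in aged cells -0.68 h. Random lists of such genes ranged from -1.27 to 0.91 h in adult and from -2.01 to 0.87 h in aged cells without the outer tails, so the aged clock mean lay inside their range.

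**Figure D3:**
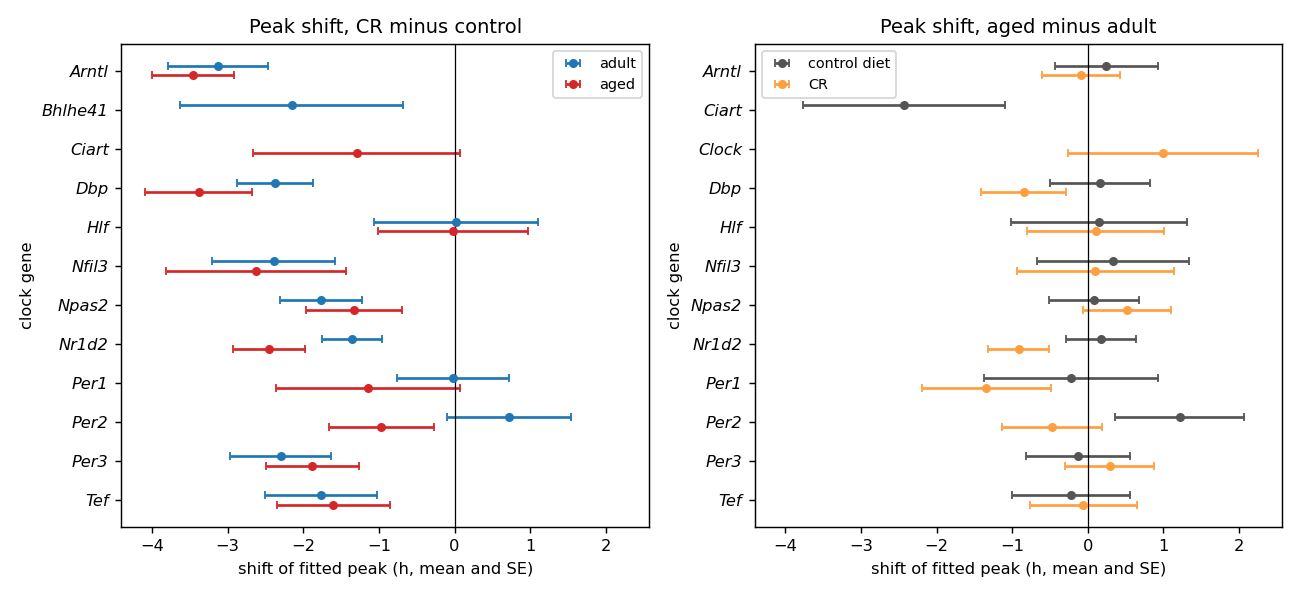
Shift of the fitted peak (h) of clock genes rhythmic in both arms compared, with SE bars, for CR minus control (left) and aged minus adult (right). Arntl lies at -3.13 h and -3.46 h on the left and at 0.24 h and -0.09 h on the right.

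Gene by gene, limma called 3 rhythm differences between diets in adult cells and 46 in aged cells (Benjamini-Hochberg, 5%). The 3 were Sphk2 (2.13 h ± 0.34 earlier, adjusted p = 0.00015), the retinaldehyde reductase gene Dhrs3 (5.69 h ± 1.06 earlier, adjusted p = 0.0014) and Dbp (adjusted p = 0.040). In aged cells, Arntl (limma adjusted p = 0.00069) and Sphk2 (limma adjusted p = 0.00069) led. Abat, which breaks down the transmitter GABA, had an amplitude of 0.11 ± 0.10 in aged control and 0.73 ± 0.10 in aged CR (limma adjusted p = 0.0050). Acaa2, an enzyme of fatty acid oxidation, peaked 7.24 h ± 1.14 earlier (limma adjusted p = 0.0058). The adult count was 8 with time as 6 levels and 6 with array weights, and the Dbp call was lost in 23 omissions of a single array. Fitted separately, the 2 aged arms gave 16 calls, with time as 6 levels 102, and without the T20 arrays 22.

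Age changed the mean level of 50 genes in the control diet. Tnc, an extracellular matrix glycoprotein, was 2.36-fold higher in aged cells (log2 1.24 ± 0.19, SE, 22 and 24 arrays, limma adjusted p = 2.2e-05). Ccn3 was 1.78-fold higher and the adhesion genes L1cam and Cadm1 were 1.61-fold and 1.53-fold higher, with limma adjusted p = 0.0021, 0.0045 and 0.0014. Olfml2a was 1.77-fold lower, the neuropeptide gene Gal 1.57-fold lower and the surface gene Thy1 1.58-fold lower, with limma adjusted p = 0.00035, 0.00035 and 0.033. In all, limma called 50 genes, 39 higher and 11 lower in aged cells. All adult arrays in this comparison carry the conflicting age tag, the Thy1 call was lost in 7 omissions of a single array, and omission of single arrays gave 20 to 74 calls and omission of T20 gave 30.

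Schwann cell markers rose with age in the control diet. Of 7 measured, 4 were higher and 3 did not pass (5 higher when adjusted over the list alone), and in omissions of a single array the call of Cnp was lost 71 times and that of Pmp22 29 times. The list had camera adjusted p = 2.9e-07 and adjusted p = 0.0078 with an estimated correlation. Sox10, a glial transcription factor, was 1.49-fold higher (limma adjusted p = 0.022) and Ngfr 1.43-fold higher (limma adjusted p = 0.0087). With the Schwann score of each array as a covariate, an alternative chosen after seeing the data, limma called 10 genes for age in the control diet and 116 within CR. The pericyte and smooth muscle list shifted up (camera adjusted p = 0.0060), with 0 of 7 called and 4 higher when adjusted over the list alone, and adjusted p = 0.27 with an estimated correlation. The interferon list shifted up (camera adjusted p = 0.019, 0 of 10 called, 0 when adjusted over the list alone), with adjusted p = 0.30 with an estimated correlation. The muscle stem cell list shifted down (camera adjusted p = 6.7e-05), with 1 of 19 lower, the Notch target Hey1 (1.31-fold, limma adjusted p = 0.034, lost in 8 omissions of a single array), and 2 lower when adjusted over the list alone. That list had adjusted p = 0.25 with an estimated correlation. By permutation of array scores, the Schwann score was higher by 0.34 (permutation p = 2e-05, adjusted p = 0.00056). The pericyte and smooth muscle score was higher by 0.24 (permutation p = 0.0055, adjusted p = 0.042). The muscle stem cell score differed by -0.11 (permutation p = 0.0030, adjusted p = 0.030). Pax7, the stem cell transcription factor, differed by -0.19 ± 0.08 (limma adjusted p = 0.37). The unfolded protein response list shifted down (camera adjusted p = 0.020, 0 of 18 called, 0 when adjusted over the list alone), with adjusted p = 0.33 with an estimated correlation.

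Within CR, where titles and age tags match, age changed 230 genes. Sncg, a synuclein, was 1.61-fold higher in aged cells (limma adjusted p = 0.00061, 32 and 26 arrays), the water channel Aqp1 1.58-fold, Tnc 1.55-fold and the neuregulin receptor Erbb3 1.52-fold, with limma adjusted p = 0.0075, 0.020 and 0.0045. The chemokine Ccl27a was 1.61-fold lower, Thy1 1.48-fold lower and Gal 1.31-fold lower, with limma adjusted p = 0.0078, 0.014 and 0.016. Limma called 230 genes, 176 higher and 54 lower. The 2 age comparisons shared 14 higher and 4 lower genes, against 0.58 and 0.05 for independent lists, and 0 genes went opposite ways. Across genes, which are not independent replicates, the age effects in the 2 diets correlated at r = 0.318, above the highest of 100 simulations without effects (0.240). If the adult control arrays came from aged mice, as tagged, their comparison would hold no age effect to share. The shared genes and this correlation therefore argue against the tags. The simulations held no factor, such as a batch, shared by the 2 arms titled adult, so one is not excluded. With matched numbers of arrays the correlation was lower. Matched numbers of arrays gave 103 calls and omission of T20 gave 118. With the pericyte and smooth muscle score as a covariate, chosen after seeing the data, limma called 54 genes.

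Some Schwann and pericyte markers were higher in aged CR cells. Of 7 Schwann markers, 2 were higher, Sox10 (1.49-fold, limma adjusted p = 0.0018) and Mbp (1.29-fold, limma adjusted p = 0.0079), and 5 were when adjusted over the list alone. The list had camera adjusted p = 0.0021 and adjusted p = 0.21 with an estimated correlation. Of 7 pericyte and smooth muscle markers, 2 were higher, the contractile genes Myh11 (1.40-fold, limma adjusted p = 0.020) and Acta2 (1.24-fold, limma adjusted p = 0.031, lost in 8 omissions of a single array), and 3 when adjusted over the list alone. That list had camera adjusted p = 0.0021 and adjusted p = 0.21 with an estimated correlation. The heat shock list shifted down (camera adjusted p = 0.011, 1 of 13 lower, 4 when adjusted over the list alone), with adjusted p = 0.68 with an estimated correlation, and its member Bag3, a co-chaperone, was 1.26-fold lower. The interferon list shifted up (camera adjusted p = 0.011, 0 of 10 called, 2 higher when adjusted over the list alone) and the ribosomal protein list down (camera adjusted p = 0.0054, 0 of 27 called, 0 when adjusted over the list alone). These had adjusted p = 0.35 and adjusted p = 0.78 with an estimated correlation. By permutation of array scores, the Schwann score was higher by 0.24 (permutation p = 1e-05, adjusted p = 0.00042). The pericyte and smooth muscle score was also higher by 0.24 (permutation p = 0.00013, adjusted p = 0.0022). The heat shock and ribosomal protein scores did not pass (permutation adjusted p = 0.062 and 0.22).

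**Figure D4:**
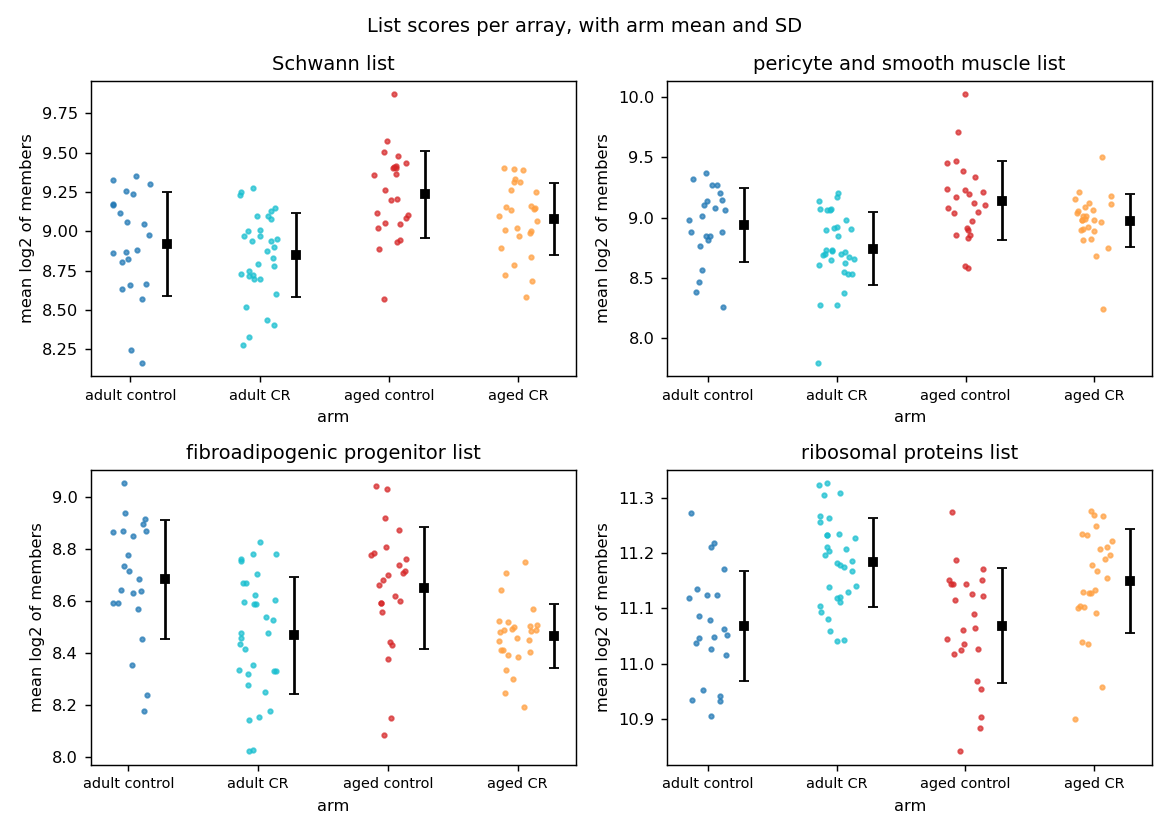
Mean log2 value of 4 gene lists per array (points) in each arm, with arm mean and SD beside them. The Schwann score averaged 8.92 in adult control, 8.85 in adult CR, 9.24 in aged control and 9.08 in aged CR.

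CR changed the mean level of 124 genes in adult cells. Thy1 was 1.85-fold lower (log2 -0.89 ± 0.15, limma adjusted p = 0.00027), the chemokine Cxcl13 1.81-fold lower (limma adjusted p = 0.00043) and Dio2, which activates thyroid hormone, 1.47-fold lower (limma adjusted p = 0.0020). Oaz2, an inhibitor of polyamine synthesis, was 1.40-fold higher (limma adjusted p = 0.00064) and Cish, a cytokine signalling suppressor, 1.35-fold higher (limma adjusted p = 0.034, lost in 8 omissions of a single array). Of the 124 genes, 65 were higher and 59 lower. If the age tags of the adult control arrays hold, this comparison, and that of rhythms between diets in adult cells, mixes age with diet. The correlation of the age effects in the 2 diets (r = 0.318, highest simulated 0.240) argues against the tags. A factor shared by the 2 arms titled adult, such as a batch, is not excluded by it. The lymphocyte score of the arrays was higher by 0.077 (permutation p = 0.0037, adjusted p = 0.032). Without adult control T0 replicate 1 the count was 188, and without adult control T16 replicate 3 it was 77. Matched numbers of arrays gave 82, and the fibroadipogenic score as a covariate, chosen after seeing the data, gave 46.

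Ribosomal protein genes rose together under CR in adult cells. All 27 measured members had a positive difference, 6 passed limma's threshold (22 when adjusted over the list alone), and camera gave adjusted p = 8.8e-20, with adjusted p = 0.028 with an estimated correlation. Rps18 rose 1.21-fold and Rpl13 1.16-fold, with limma adjusted p = 0.0092 and 0.025. In omissions of a single array the call of Rpl13 was lost 3 times, that of Rps19 13 times and that of Rps4x 14 times. The fibroadipogenic list fell, with 3 of 9 lower (4 when adjusted over the list alone), camera adjusted p = 1.2e-06 and adjusted p = 0.0096 with an estimated correlation. Dpt, a matrix protein gene, fell 1.18-fold and Gsn 1.13-fold, the latter lost in 2 omissions of a single array. The fibroadipogenic score of the arrays was lower by -0.21 in the time-adjusted comparison (permutation p = 0.00038, adjusted p = 0.0053). Of 23 extracellular matrix genes 4 were lower (7 when adjusted over the list alone), with camera adjusted p = 1.3e-07 and adjusted p = 0.052 with an estimated correlation. Antigen presentation and complement genes had 0 of 11 called and 3 lower when adjusted over the list alone, with camera adjusted p = 0.00026 and adjusted p = 0.0096 with an estimated correlation. The unfolded protein response list (1 of 18 lower, 8 lower and 2 higher when adjusted over the list alone, camera adjusted p = 0.00079) had adjusted p = 0.097 with an estimated correlation. The heat shock list (0 of 13 called, 1 lower when adjusted over the list alone, camera adjusted p = 0.019) had adjusted p = 0.42 with an estimated correlation.

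Thy1 and Cxcl13 were also lower under CR in aged cells. Cxcl13 was 1.75-fold lower, Thy1 1.74-fold lower and the protease inhibitor gene Serpina3n 1.68-fold lower, each with limma adjusted p = 0.00076. Kcnj8, a potassium channel of pericytes, was 1.71-fold lower and Tnc 1.61-fold lower, with limma adjusted p = 0.0012 and 0.017. Rtl3 was 1.67-fold higher, Milr1 1.63-fold and Ntrk3, a neurotrophin receptor, 1.51-fold, with limma adjusted p = 0.00078, 0.0030 and 0.040. The Ntrk3 call was lost in 19 omissions of a single array. Limma called 272 genes, 143 higher and 129 lower. The 2 diet comparisons shared 12 higher and 17 lower genes, against 0.78 and 0.64 for independent lists, and 0 went opposite ways. Without the T20 arrays there were 145 calls.

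Gene groups moved in aged cells under CR as follows. All 27 measured members of the ribosomal protein list had a positive difference, with 0 called and 8 higher when adjusted over the list alone (camera adjusted p = 7.7e-09, adjusted p = 0.24 with an estimated correlation). The heat shock list shifted down, with 3 of 13 lower and 7 when adjusted over the list alone (camera adjusted p = 0.00032, adjusted p = 0.24 with an estimated correlation). Its small chaperone Hspb1 was 1.18-fold lower and Hsph1 1.27-fold lower, with limma adjusted p = 0.020 and 0.038, the latter lost in 13 omissions of a single array. Lower lists were also extracellular matrix, with 3 of 23 called (5 when adjusted over the list alone), and fibroadipogenic, with 1 of 9 (3 when adjusted over the list alone), at camera adjusted p = 0.00071 and 0.0022. They had adjusted p = 0.24 and adjusted p = 0.24 with an estimated correlation, and Sparc, a collagen-binding matrix protein, was 1.18-fold lower (limma adjusted p = 0.00097). The Schwann list shifted down, with 1 of 7 lower, Ncam1, whose call was lost in 30 omissions of a single array (3 when adjusted over the list alone, camera adjusted p = 0.0054, adjusted p = 0.24 with an estimated correlation). The unfolded protein response list shifted down, with 1 of 18 lower (5 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.37 with an estimated correlation). By permutation of array scores, the ribosomal score differed by 0.079 (permutation p = 0.0032, adjusted p = 0.030). The heat shock score differed by -0.15 (permutation p = 1e-04, adjusted p = 0.0021) and the fibroadipogenic score by -0.19 (permutation p = 0.00057, adjusted p = 0.0068). The Schwann score did not pass (-0.15, permutation p = 0.012, adjusted p = 0.079).

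No member of 3 further lists passed in aged cells under CR. The sterol and fatty acid synthesis list had 13 of 13 positive differences and 1 higher when adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.37 with an estimated correlation). The immediate early list had 16 of 20 positive differences and 0 called when adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.38 with an estimated correlation). The Notch list had 11 of 13 positive and 0 called when adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.24 with an estimated correlation).

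The last comparison asked whether CR turned age changes back. In the control diet, 9 genes changed with age and in the opposite direction with CR in aged mice. Higher with age and lower with CR were Tnc, Cadm1, L1cam, Olig1, Ednrb, Ncmap, Col16a1 and Kmt5a, and the reverse held for Rasl10a, whose age call was lost in 23 omissions of a single array. These names include genes outside the naming rule, chosen after their values were seen. Independent lists would give 0.42 genes up and then down and 0.13 down and then up. The aged control arrays enter both comparisons. In 100 simulations without effects the count was 0, which says nothing of the bias for genes with a real age effect. With the aged controls split by replicate number, so that the groups compared shared no arrays, the count of genes turned back was 0 and 1 (8 and 8 called for age, 0 and 109 for diet), and the correlation across genes was -0.158 and -0.0915. Of the genes called for age there, 8 and 6 had the opposite sign in the diet comparison. With all aged controls, the correlation of the 2 effects across genes was -0.361 against a simulated median of -0.496, and the covariance was -0.0051 against -0.0037 (range of simulations -0.0058 to -0.0015). No gene passed limma's test of the interaction of age and diet (0 called, 908 at an unadjusted p under 0.05). Its smallest p values belonged to Olig1, a glial factor (-0.49 ± 0.11, adjusted p = 0.115), and Rasl10a (0.56 ± 0.12, adjusted p = 0.115). Leaving out single arrays gave 3 to 17 genes turned back, leaving out T20 gave 5, separate fits gave 1, and the Schwann score as a covariate gave 2.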

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

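The tests of chance regroupings, of peak shifts and of the share of stem cells were chosen after the results were seen. The tests of covariation of Schwann markers, of matched array numbers and of the spread per arm were chosen before their results were seen.

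Each count of genes was set against 100 relabellings of the arrays, the real grouping included. Arrays were relabelled singly, so a factor shared by the arrays of a time point or an arm cannot be excluded this way. Chance labelling of single arrays is excluded for the rhythmic genes, where only 1 of 100, the real grouping, reached the count. It was 1256 in adult control against at most 5 in the others, and 2650 in adult CR against 1. In aged control it was 1276 against 3, and in aged CR 1951 against 2. The same holds for the level differences, with 1 of 100 each: 50 for age in the control diet against at most 1, 230 for age in CR against 3, 124 for diet in adult cells against 1 and 272 for diet in aged cells against 2. It also holds for the rhythm differences between diets in aged cells, 46 against at most 1. In adult cells 3 were called against at most 1, also with 1 of 100, but that count rests on few signals. The annotated spans of Sphk2 and Dbp among them overlap, and the Dbp call was lost in 23 omissions of a single array. Chance is not excluded for the rhythm difference with age within CR (1 gene, 7 of 100, highest other 1). For the interaction (highest other 3) and the rhythm difference with age in the control diet (highest other 1) the count was 0, which 100 of 100 relabellings reach by construction, so nothing was tested there.

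Of 7 Schwann cell markers, 4 were higher in aged cells in the control diet and 2 within CR, where the list had adjusted p = 0.21 with an estimated correlation. The Schwann score of the arrays was higher by 0.34 in the control diet (permutation p = 2e-05, adjusted p = 0.00056). Within CR it was higher by 0.24 (permutation p = 1e-05, adjusted p = 0.00042). A lower share of stem cells in the aged preparations would raise the markers of the other cell types alike, and 7 of 8 other lists rose less than the Schwann list. As 6 of these 7 are dim (mean log2 4.99 to 6.00), where differences are understated, the argument against it rests on the bright fibroadipogenic list (-0.0086 against 0.34 in the control diet, permutation p = 7e-05, adjusted p = 0.00021). The pericyte and smooth muscle list did not separate from it (0.24 against 0.34, permutation p = 0.382). The muscle stem cell score was itself lower in aged cells in the control diet (-0.11, permutation p = 0.0030, adjusted p = 0.030). Within CR it differed by -0.027 (permutation p = 0.37, adjusted p = 0.65). A part played by a lower share of stem cells in the control diet therefore stays open. A varying number of Schwann cells may account for the pattern, since members varied together within groups with a mean correlation of 0.268, against a median of 0.038 in random lists, few of which exceeded 0.136 (highest 0.296), although Ncam1, also made by muscle stem cells, did not rise (-0.02 ± 0.04). Whether aged muscle holds more such cells or the stem cells themselves express these genes was not tested and stays open.

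More rhythmic genes were called under CR than in the control diet. With 21 arrays in each arm (1108 and 952 in the control diet, 1453 and 1232 under CR), 6 of 100 exchanges of diet labels, the real grouping included, reached as large an excess (highest other 1159), so array numbers together with chance may account for it. At these numbers the residual spread differed by -0.0031 in adult and by -0.00058 in aged cells (CR minus control). Both lay inside the range of the regroupings (lowest -0.017 and -0.028). With all arrays the spread was 0.259 in adult CR against 0.262 in adult control, but 0.268 in aged CR against 0.265 in aged control. A part played by lower spread stays open in adult cells, whereas with all arrays the spread of aged CR was not lower. An effect of the diet also stays open, as the excess was not tested in other mice.

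Clock genes peaked earlier on average under CR. Chance assignment of mice is excluded at permutation p = 0.00017 in adult and 1e-05 in aged cells. A common shift of collection time would move all rhythmic genes alike. In adult cells the clock's mean of -1.503 h lay below the range of random lists of genes rhythmic in both diets (-1.27 to 0.91 h without the outer tails). The random list p was 0.017, and the median shift of all 708 such genes was -0.09 h. These values argue against a common shift in adult cells. Random lists hold no variation shared by the clock genes, so their range may be too narrow for such a list. In aged cells the mean of -1.83 h lay inside that range (-2.01 to 0.87 h) while the median of all such genes was -0.68 h, so a common shift and a shift of the clock cannot be told apart there.

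Rhythms that differed between groups by a test of the difference had these limma adjusted p values. Between ages within CR it was 0.020 for Fzd7. Between diets in adult cells it was 0.00015 for Sphk2, 0.0014 for Dhrs3 and 0.040 for Dbp. Between diets in aged cells it was 0.00069 for Arntl, 0.00069 for Sphk2, 0.0050 for Abat, 0.0058 for Acaa2, 0.0058 for Gpnmb, 0.0093 for Sec22b, 0.011 for Creb3l1 and 0.011 for H2-DMa.

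Arrays that stood far from the others of their arm and time were sought in 21 measures and 23 groups. They numbered 23 of 483 tests, where chance gives about 24.2. The median of all probe sets stood apart in adult control T0 replicate 3 (5.00), aged CR T0 replicate 3 (4.87) and adult CR T16 replicate 1 (4.94), and the 3′ minus 5′ difference of the Gapdh control probes in aged control T12 replicate 4 (0.34), adult CR T0 replicate 4 (0.089) and adult CR T12 replicate 1 (-0.32). The muscle stem cell score did in aged control T16 replicate 2 (9.25) and T4 replicate 1 (9.25), the commitment score in adult CR T20 replicate 3 (6.39) and the myofibre score in adult CR T4 replicate 2 (7.54, others 5.94 to 6.24). The fibroadipogenic score stood apart in aged control T8 replicate 4 (9.03), the lymphocyte score in adult CR T20 replicate 5 (5.68), the neutrophil score in aged control T12 replicate 4 (4.68), the pericyte score in aged CR T12 replicate 4 (8.69) and adult CR T12 replicate 4 (8.28), and the tenocyte score in aged CR T20 replicate 1 (6.97). The heat shock score did in adult control T16 replicate 1 (9.53) and aged CR T12 replicate 3 (9.12), and the glucocorticoid-induced score in adult control T16 replicate 2 (9.17), aged CR T4 replicate 1 (9.49) and aged control T4 replicate 4 (9.57). The immediate early score stood apart in adult control T0 replicate 3 (9.96) and T12 replicate 2 (10.4).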

How the results depend on the processing

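The covariates made of cell type scores were chosen after seeing the data, and the other alternatives before. Causes of the changes below were not tested, except that fewer arrays or genes enter where stated. Without a filter on dim probes (17097 genes) the age calls in the control diet numbered 30 and the rhythm differences with age there 1. With the mean of a gene's probes, the rhythm differences with age in CR numbered 0. Separate fits of the arms compared gave 28 age calls in the control diet, 16 rhythm differences with diet in aged cells, 1 gene turned back and 289 genes rhythmic in both control arms. With time as 6 levels, the interaction called 1, the rhythm differences were 2 for age in CR, 8 for diet in adult and 102 for diet in aged cells, and 15 genes turned back. Without the T20 arrays, 836 genes were rhythmic in aged control, age calls were 30 in the control diet and 118 in CR, diet calls in aged cells 145, rhythm differences 0 for age in CR and 22 for diet in aged cells, and 5 genes turned back. Matched numbers (84 arrays) gave 1453 rhythmic genes in adult CR, 1232 in aged CR, 103 age calls in CR, 82 diet calls in adult cells, 0 rhythm differences with age in CR and r = 0.246 between the age effects. Array weights gave 0 and 6 rhythm differences for age in CR and diet in adult cells. The first residual component (5.81% of the residual variance), which by construction leaves every estimate in place, gave 10 for age in CR and 106 for diet in aged cells. The rank-based test called 10, 1525, 197 and 543 rhythmic genes in adult control, adult CR, aged control and aged CR, with 8 in common between the control arms. List calls on levels numbered 25 with the preset and 4 with an estimated correlation, and list calls on rhythms 12, against 9 with the rank-based test. Over all alternatives, 3790 results on named genes kept direction and side of the threshold, 289 lost and 45 gained a call, and 9 reversed.

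With the Schwann score as covariate, 773 genes were rhythmic in adult control, 259 in both control arms, 10 changed with age in the control diet and 116 in CR, 2 turned back, and the age effects correlated at 0.395. With the pericyte score, age calls were 20 in the control diet and 54 in CR, and rhythm differences with age in CR 0. With the fibroadipogenic score, 46 genes changed with diet in adult cells and 4 turned back. In 9 cases a named gene's sign reversed under these covariates. With the Schwann score, the age difference in the control diet became -0.027 for Sox10, -0.031 for Pmp22 and -0.091 for Cnp, that of Cnp in CR -0.14, and the diet difference of Mbp in aged cells 0.051. With the pericyte score, the age difference in the control diet became -0.013 for Pdgfrb and -0.063 for Rgs5, and that of Rgs5 in CR -0.12. With the fibroadipogenic score, the diet difference of Col1a1 in aged cells became 0.0086. Each of these genes is itself a member of the score used, so part of its own change is removed by construction.

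The replicate numbers showed little pairing of the arrays. Arrays of the same age, time and number in the 2 diets correlated at a median of 0.046 in adult and 0.021 in aged cells. Pairs of other numbers had medians of -0.0011 and 0.0072. Of the same-number pairs, 4 of 21 and 6 of 24 were over 0.1, and 6 and 9 arrays correlated best with their own number. This check cannot exclude that numbers mark a shared day. The replicate block as a random effect (correlation 0.049) gave 73 rhythm differences with diet in aged cells, and fixed pairs gave 193 diet calls in adult and 140 in aged cells.

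Leaving out each array in turn gave 962 to 1312, 2407 to 2725, 1032 to 1322 and 1747 to 2000 rhythmic genes in adult control, adult CR, aged control and aged CR, and 355 to 471 common to the control arms. Level calls ranged from 20 to 74 for age in the control diet, 174 to 255 for age in CR, 77 to 188 for diet in adult and 201 to 311 for diet in aged cells, and 0 to 1 for the interaction (1 without aged control T8 replicate 2). Rhythm differences ranged from 0 to 0 and 0 to 1 for age in the control diet and CR, and 2 to 5 and 33 to 63 for diet in adult and aged cells. Genes turned back ranged from 3 to 17 and the agreement r from 0.295 to 0.339. Age calls in the control diet moved by over 1.5 times without adult control T0 replicate 2 (30) or 3 (32), T8 replicate 4 (31), T12 replicate 3 (28) or T16 replicate 4 (29), and aged control T4 replicate 1 (31) or 3 (25), T8 replicate 1 (31), T16 replicate 2 (20) or 4 (33) or T20 replicate 4 (27). Genes turned back did so without aged control T4 replicate 1 (4), T12 replicate 4 (14), T16 replicate 1 (15) or 2 (3), or T20 replicate 2 (17) or 4 (4). The Fzd7 call went without aged CR T8 replicate 2 or 3, T20 replicate 1, 2 or 3, or adult CR T20 replicate 4, and without adult CR T4 replicate 5 the diet rhythm differences in adult cells were 5. Of 296 results on named genes, 48 lost their call without some array and 0 changed sign.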

Other observations

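Of the 29 genes that changed with CR in the same direction at both ages, some of those not yet described are named here after their values were seen. Higher under CR were the ribosomal protein genes Rpl36a (0.37 in adult and 0.26 in aged cells on the log2 scale) and Rpl21 (0.15 and 0.16), which are not members of the fixed ribosomal protein list, and Snhg8 (0.24 and 0.20) and Snhg5 (0.26 and 0.23), which host small nucleolar RNAs. Lower under CR were Osmr, the oncostatin M receptor (-0.46 and -0.41), Nid1, a basement membrane gene (-0.38 and -0.41), and Anxa5 (-0.19 and -0.22). Each passed limma's test at both ages.

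Of the 18 genes that changed with age in both diets, these were also picked after their values were seen, and no list was tested on them. Gpm6b was higher by 0.55 in the control diet and 0.44 in CR, Lgi4 by 0.41 and 0.42, Pllp by 0.45 and 0.36, and Aspa by 0.45 and 0.32. The score of sterol and fatty acid synthesis genes peaked at 2.89 h in adult control, 22.2 h in adult CR, 1.87 h in aged control and 20.7 h in aged CR, and the glucocorticoid-induced score at 10.7, 11.5, 11.6 and 10.4 h in the same order. These score peaks were not tested against each other.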
